A study of Homo sapiens with 8 samples.

How the data were processed

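The data are 8 hybridizations of radiolabelled cDNA to nylon membranes spotted with cDNA clones: the NCI-H460 sublines N15 and LNM35, each hybridized 2 times to the filter types GF200 and GF201. Per the labels, total RNA was reverse transcribed with a radioactive phosphorus label, filters were scanned on a phosphorimager, images were processed with L Process and signal intensities were quantified with ArrayGauge. For 1 hybridization, the first of N15 on GF201, the labels also describe RNA extraction from tumour tissue sections, which does not match a subline; its other labels name the subline, the sources used here do not settle which holds, and values without it are among the alternatives. Versions of these programs, the treatment of background and any scaling are not given in the sources used here. The deposited intensity values lie on a linear scale with 2 decimals, are all above 0, and were not equalised between hybridizations: medians on GF200 were 0.14 and 0.16 for N15 and 0.12 and 0.08 for LNM35, and on GF201 0.18 and 0.17 for N15 and 0.26 and 0.11 for LNM35. Whether background was subtracted changes what a ratio of dim spots means, since a shared background shrinks it. Per the labels, the repeat used a newly labelled probe of the same sample after stripping, so repeats share their RNA. The labels do not say whether both sublines used one filter; if each had its own, differences between filters and between sublines cannot be separated.

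Spot numbers run to 5584 and 5352 have a value on each filter type; the other 232 were not analysed here. Spots were named through the platform annotation, with symbols updated by gene identifier against the RefSeq table of GRCh38.p14. On GF200, 3170 spots have a single gene symbol, 133 several and 2049 none here; 3163 of the single symbols matched RefSeq. On GF201, 3310 have a single symbol, 131 several and 1911 none here; 3296 matched. Spots with several symbols were not named. The annotation covers 2864 genes on GF200 and 2999 on GF201.

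Each filter type was analysed alone. Intensities were taken to log2 without an offset and quantile-normalized between the 4 hybridizations, and LNM35 was compared with N15 per spot with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the spots of the filter type and a threshold of 0.05. A change is LNM35 minus N15, so that positive values are higher in LNM35, and its error is limma's moderated standard error with n = 2 hybridizations per subline. The number of hybridizations limits the precision. A second rule of size counted spots whose 4 ratios of single hybridizations were all at least 2-fold in one direction, with a tolerance of 1e-09 log2. Data were simulated with the spot means found here and a variance for each spot drawn from limma's fitted prior. These variances were unlinked to signal, so the rates do not tell bright from dim spots. In these data limma found 25 of 50 GF200 spots changed by 4 log2, 6 of 50 changed by 3 and 0 of 50 changed by 2. On GF201 it found 41, 22 and 3 of 50, and 1 of 50 at a change of 1. Among 5152 unchanged spots it called 0 on GF200 and 3 on GF201, and the rule of size passed 102 and 87.

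For gene lists, a gene was represented by its spot with the highest rank of mean signal, and a list's median log2 change was placed among 10000 random lists of the same size matched on filter type and signal decile (a permutation of gene names within these classes), two-sided, with Benjamini-Hochberg adjustment over the 28 of 29 lists with at least 5 measured genes; the remaining list holds the genes tied to this pair of sublines before. In simulated use, 4.50% of random lists of 25 genes had p under 0.05, and 98.5% after a shift of 0.5 log2. Changes on both filter types were compared by Pearson and Spearman correlation with 100000 permutations of genes. The same matched random sets served for genes of a chromosome. Calculations outside R used Python, numpy, pandas and matplotlib.

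Genes named in the text follow a rule fixed, with the lists and tests, before the data were examined. Per filter type, these are the 7 genes with the largest change in each direction among spots past the threshold with 4 ratios of one sign and a single gene symbol, filled up by size where fewer pass, as here throughout. Per list, up to 4 members past the threshold or else the 2 with the largest absolute change are named, and PTGS2, DCBLD2 and DLX4 always. HSP90AB1, USP9X, CTBP2, COPB2 and FOSL2 were named after their values were seen. Alternatives were median scaling, the deposited intensities, cyclic loess, an offset of each hybridization's 10th percentile, leaving out the lowest 25% or 50% of spots by mean signal, an intensity trend or robust fit in the variance prior, the hybridization number as a block, adjustment over both filter types together, averaging a gene's spots, and leaving out each hybridization.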

Results

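Transcript levels were compared between a pair of sublines of the human large cell lung carcinoma line NCI-H460: LNM35, which metastasizes readily, and N15, which metastasizes rarely. Radiolabelled cDNA of each subline was hybridized 2 times to each of 2 nylon filter types, GF200 and GF201, whose cDNA clones differ in large part, giving 8 hybridizations. The labels describe each repeat as a newly labelled probe of the same sample on a stripped filter, so the spread between repeats is technical, and every p-value compares single RNA samples of the sublines rather than independent cultures. For the first N15 hybridization on GF201 the labels also hold an extraction text for tumour tissue, at odds with a subline. Without it N15 has 1 hybridization on GF201. Of the changes given below, CDH11 then had -5.11 and CXCL1 4.84 and 3.95. TUBA3D went from 3.85 to 6.06, GNAS from 2.67 to 3.66, a PSMD2 spot from 2.92 to 3.84, AARS1 from -1.79 to -1.27, a PTGS2 spot from 1.37 to 0.94 and CPE from 1.35 to 0.62. Each filter type gave intensities for 5352 spots. Intensities summed over a hybridization to between 17838 and 22002 on GF200 and between 26631 and 46486 on GF201. Dim spots were measured coarsely: on GF200 29.2% to 55.5% of spots lay under 0.1, and on GF201 17.3% to 44.3%. Repeats of LNM35 on GF201 differed by a median of 0.103 log2 in the brightest 10% of spots and by 0.447 in the dimmer 50% of spots. The corresponding values for N15 on GF200, the least repeatable pair, were 0.242 and 0.604. Over all spots, N15 repeats differed by 0.60 on GF200, against 0.47 to 0.56 between single hybridizations of the 2 sublines. On GF201 these values were 0.47 against 0.42 to 0.49. The LNM35 repeats differed by less, 0.43 on GF200 and 0.38 on GF201.

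The question on each filter type was which transcripts differ between the highly and the rarely metastatic subline. On GF201, CXCL1, a chemokine that attracts neutrophils, stood farthest above N15 in LNM35. Its spots from 2 clones were 4.33 ± 0.42 and 4.02 ± 0.31 log2 higher in LNM35 (SE, n = 2 hybridizations per subline), with intensities of 9.06 and 4.18 in LNM35 against 0.37 and 0.19 in N15 at the spot farthest apart. CDH11, which encodes the cell adhesion molecule cadherin 11, had a log2 change of -5.08 ± 0.27 (LNM35 minus N15), with intensities of 3.61 and 2.82 in N15 and 0.14 and 0.07 in LNM35, under the LNM35 medians of 0.26 and 0.11 over all spots. Neither met the threshold over all spots: the limma adjusted p was 0.102 for CDH11 and 0.491 and 0.287 for the CXCL1 spots. PDK4, a kinase that restrains pyruvate dehydrogenase, measured 3.60 ± 0.49 log2 higher in LNM35, from N15 intensities of 0.07 and 0.12 that lie under the N15 medians of 0.18 and 0.17 over all spots. CPLX2, encoding the synaptic protein complexin 2, measured 3.14 ± 0.42 higher, although a second, dim CPLX2 spot differed by -0.13. The proteasome subunit gene PSMD2 measured 2.92 and 2.41 higher at 2 spots, and ALG3, a mannosyltransferase gene of N-glycan assembly, 2.84 ± 0.40 higher. GNAS, encoding the stimulatory G protein alpha subunit, measured 2.67 ± 0.66 higher, from N15 intensities of 0.16 and 0.05, also under those medians. TUBA3D, an alpha-tubulin gene, measured 3.85 ± 1.47 higher, but its N15 intensities of 3.37 and 0.17 disagreed.

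Among the lowest in LNM35 on GF201 were 4 genes of cytosolic aminoacyl-tRNA synthetases, the enzymes that charge tRNAs with amino acids. The log2 changes were -3.19 ± 0.44 for WARS1, -2.61 ± 0.28 for GARS1, -2.36 ± 0.42 for SARS1 and -1.79 ± 0.46 for AARS1. DUSP6, a phosphatase that inactivates ERK, had a change of -2.23 ± 0.50, and LGALS3, encoding galectin 3, a change of -1.98 ± 0.30 at intensities of 33.38 and 30.17 in N15 and 14.77 and 6.42 in LNM35. At 388 of 5352 GF201 spots the unadjusted limma p was under 0.05, and at 108 on the deposited intensities. Such counts include spots that reach this without any difference. By limma with Benjamini-Hochberg adjustment 0 of 5352 GF201 spots passed. The count was 21 with median scaling, 15 higher and 6 lower, 7 on the deposited intensities, 6 higher and 1 lower, 13 with an intensity trend in the variance prior, 8 higher and 5 lower, and 1, lower, with an offset; both CXCL1 spots and CDH11 were among those of median scaling, the deposited intensities and the trend, and the offset called CDH11 alone.

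By size alone, 94 GF201 spots lay at least 2-fold apart in one direction in all 4 LNM35-to-N15 ratios of single hybridizations, 62 higher and 32 lower in LNM35. The higher spots made up 66.0% of these, against 43.6% on the deposited intensities. Noise simulated with spot variances drawn from the fitted prior, unlinked to signal, put 87 of 5152 unchanged GF201 spots past the same rule. The other 2 ways of splitting the 4 hybridizations into 2 and 2 gave 46 and 37 spots, fewer than the 94. With 3 splits in all, the count by itself does not separate the sublines from technical noise. Leaving out any single hybridization leaves 2 ratios to satisfy and gave 260 to 480 spots.

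**Figure D1:**
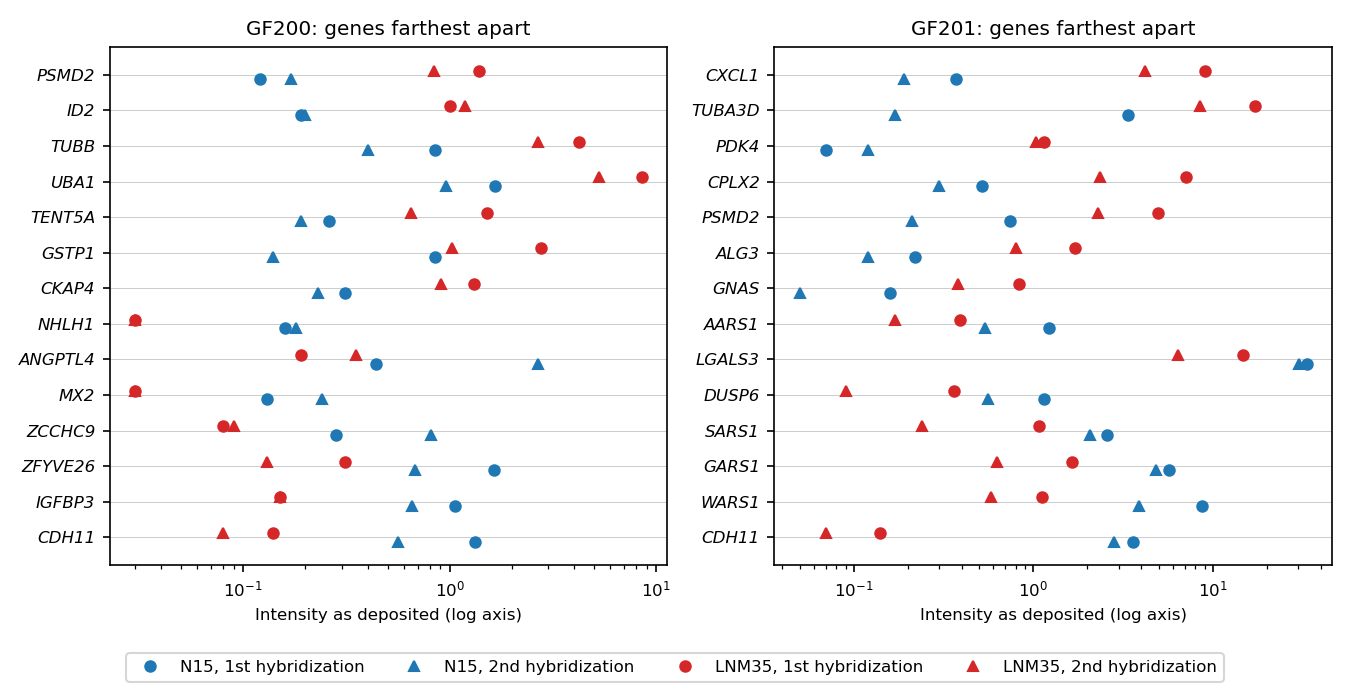
Intensity as deposited (horizontal log axis) of the 7 genes farthest above and the 7 farthest below N15 in LNM35 on each filter type, ordered by log2 change, with a point for each hybridization (blue N15, red LNM35). CXCL1 reads 9.06 and 4.18 in LNM35 against 0.37 and 0.19 in N15, and CDH11 on GF201 reads 0.14 and 0.07 against 3.61 and 2.82.

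On GF200, the gene farthest above N15 was PSMD2, at 3.29 ± 0.35 log2 (SE, n = 2 hybridizations per subline), with intensities of 1.38 and 0.84 in LNM35 and 0.12 and 0.17 in N15. ID2, a helix-loop-helix inhibitor of differentiation, measured 2.77 ± 0.39 higher in LNM35. UBA1, the ubiquitin-activating enzyme gene, measured 2.51 ± 0.54 higher, with intensities of 8.53 and 5.30 in LNM35 against 1.66 and 0.96 in N15. The other genes farthest above N15 were TUBB, a beta-tubulin gene, at 2.57 ± 0.65, TENT5A, a poly(A) polymerase gene, at 2.47 ± 0.49, GSTP1, a glutathione transferase gene, at 2.42 ± 1.15 but with N15 intensities of 0.85 and 0.14 and single ratios from 0.34 to 4.50, and CKAP4, encoding a membrane protein of the endoplasmic reticulum, at 2.29 ± 0.45. TUBB had no counterpart of this difference on GF201, where its very bright spot changed by -0.04, and a second, dim TENT5A spot differed by -0.22.

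CDH11 was lowest in LNM35 on GF200 as on GF201, with a log2 change of -2.65 ± 0.68 from another clone. IGFBP3, encoding a binding protein of insulin-like growth factors, had a change of -2.09 ± 0.55. ZFYVE26, encoding spastizin, read 0.31 and 0.13 in LNM35 against 1.63 and 0.68 in N15, and its change ran from -3.01 to -1.15 with 1 hybridization left out. The changes were -1.99 ± 0.53 for ZCCHC9, a zinc finger gene, and -1.95 ± 0.39 for the interferon-induced MX2. For ANGPTL4, an inhibitor of lipoprotein lipase, the change was -1.95 ± 0.94, with N15 intensities of 0.44 and 2.69. NHLH1, a neuronal helix-loop-helix gene, had a change of -1.94 ± 0.34. MX2 and NHLH1 read 0.03 in both LNM35 hybridizations, under the medians of 0.12 and 0.08 there. By limma with Benjamini-Hochberg adjustment 0 of 5352 GF200 spots passed, with adjusted p = 0.794 at the lowest. An unadjusted limma p under 0.05 was found at 324 spots, and at 472 on the deposited intensities. Median scaling called 3 GF200 spots, all higher, of which PSMD2 was the only one with a gene name here.

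On GF200, 116 spots met the 2-fold rule of size, 72 higher and 44 lower in LNM35. The higher share of 62.1% depended on the scaling: it was 80.7% of 171 spots with median scaling, 9.01% of 233 on the deposited intensities and 74.4% of 39 with an offset. Noise simulated in the same way put 102 of 5152 unchanged GF200 spots past the rule, while the other 2 splits of the hybridizations gave 63 and 35. Leaving out any single hybridization gave 338 to 790 spots. The median GF200 spot changed by -0.02 log2 after quantile normalization, by 0.19 with median scaling and by -0.42 on the deposited intensities, so that changes are relative to the scaling chosen.

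**Figure D2:**
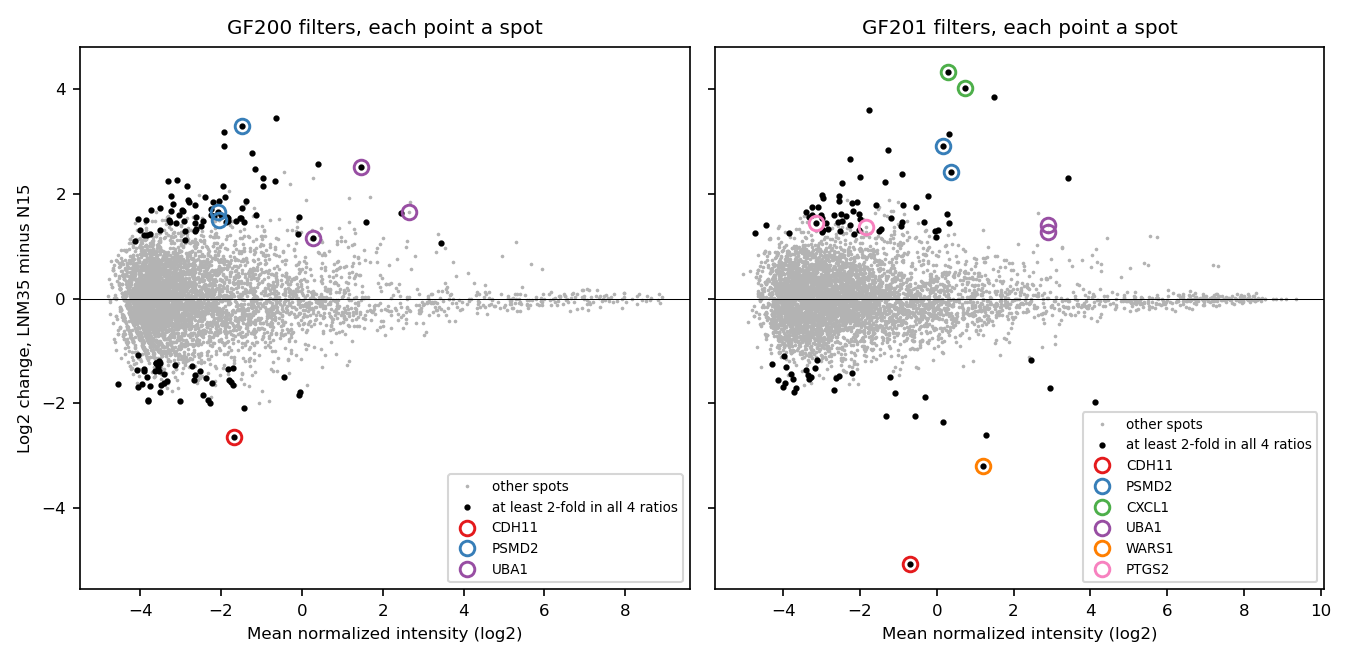
Log2 change (LNM35 minus N15) against mean normalized log2 intensity, each point a spot, with black points for spots at least 2-fold apart in one direction in all 4 ratios and coloured circles for named genes. CDH11 lies lowest on both filter types, at -2.65 on GF200 and -5.08 on GF201, and the 2 CXCL1 spots lie highest among named genes on GF201, at 4.33 and 4.02.

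Genes tied to this pair of sublines before were read beside these. PTGS2, encoding the prostaglandin synthase cyclooxygenase 2, measured higher in LNM35 at both of its GF201 spots, by 1.37 ± 0.44 and 1.44 ± 0.30 log2 from 2 clones (SE, n = 2 hybridizations per subline). These spots are dim: the second read 0.08 and 0.07 in N15, and the first 0.13 and 0.23, against N15 medians of 0.18 and 0.17. DLX4, a homeobox gene, had a change of -1.27 ± 0.50 on GF200, at a spot beside one that was 7.44 log2 brighter. Its N15 intensities were 2.02 and 4.83, and its change ran from -1.81 to -0.79 with 1 hybridization left out. DCBLD2, encoding a neuropilin-like membrane receptor, measured 0.44 ± 0.33 and 1.19 ± 0.42 higher on GF200 and 0.15 ± 0.29 higher on GF201, the last with the other sign when the first N15 hybridization was left out. By limma the adjusted p was 0.653 at each PTGS2 spot, 0.794 for DLX4 and between 0.794 and 0.951 for the DCBLD2 spots, so 0 of these genes passed.

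Genes with spots on both filter types, or with several spots, show how far separate measurements of a gene agree. CDH11 and PSMD2 met the 2-fold rule on both filter types, at changes of -2.65 and -5.08 for CDH11 and 3.29 and 2.41 for PSMD2 by the brightest spot of each. All 5 PSMD2 spots, from 2 clones, measured higher in LNM35, between 1.49 and 3.29 log2. All 5 UBA1 spots, also from 2 clones, did so too, between 1.15 and 2.51, and all 4 spots of HSP90AB1, a chaperone gene carried by 1 clone, between 0.73 and 2.25. These spots are mostly repeats of a clone. A single PSMD2 clone gave every spot except that at 3.29, with 1.49 and 1.66 on GF200 and 2.92 and 2.41 on GF201. For UBA1 a single clone gave every spot except that at 1.15. Most genes past the rule on a filter type did not repeat so. By the brightest spots, 16 genes with spots on both filter types met the rule on at least 1 of them, 2 on both, and 11 of the other 14 changed by under 0.5 log2 on the other filter type. USP9X, a deubiquitinase gene, measured 1.85 on GF200 and 0.27 on GF201, and CTBP2, a transcriptional corepressor gene, 1.84 and 0.20. In contrast, mean changes had one direction on GF200 and GF201 for COPB2 (1.30 and 1.46), FOSL2 (-1.06 and -1.43) and HSP90AB1 (1.56 and 0.73). These genes met the rule on 1 filter type only. Within a filter type, the changes of different clones of a gene correlated across genes with r = 0.130 on GF200 (185 genes, permutation p = 0.0758, adjusted p = 0.0758 over 4 relations) and r = 0.304 on GF201 (236 genes, permutation p = 6e-05, adjusted p = 8e-05). By rank the agreement was weaker on both, with Spearman's rho = 0.071 on GF200 (permutation p = 0.337) and 0.120 on GF201 (permutation p = 0.0649), unadjusted. For the same clone at 2 spots r was 0.54 on GF200 (103 clones) and 0.62 on GF201 (53 clones), with permutation p = 1e-05 for both, the smallest these permutations can give, and adjusted p = 2e-05. In a count chosen after the values were seen, 5 genes had 2 or more spots past the 2-fold rule in one direction: CXCL1, HSP90AB1, PSMD2 and UBA1 higher, and CDH11 lower. Shuffling changes among the spots of 775 genes with several spots gave 0.594 such genes on average and 4 at most in 1000 shuffles, and no gene had spots past the rule in both directions. The shuffle ignored signal and shared clones, so agreement of 1 clone at 2 spots, as for HSP90AB1, also exceeds it. It thus does not by itself show a difference between the sublines. With median scaling the count was 8, 7 higher and 1 lower, and on the deposited intensities 4, 2 higher and 2 lower, of which 3 were among these 5.

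Over the 413 genes with spots on both filter types the log2 changes correlated across genes with Pearson's r = 0.230 (permutation p = 2e-05, adjusted p = 6e-05 over 6 relations) and Spearman's rho = 0.0942 (permutation p = 0.0560, adjusted p = 0.112), and 52.1% had one sign on both. Without CDH11 and PSMD2, which are also the 2 genes farthest from the median on GF200, r was 0.116 (permutation p = 0.0189, adjusted p = 0.0232). Among the 149 genes in the upper 50% of signal on both filter types r was 0.467 (permutation p = 1e-05, the smallest these permutations can give) and rho 0.300. Without the first hybridizations r was 0.126 and rho 0.0497, and without the second 0.156 and 0.0459. For the 41 genes with the same clone on both filter types r was 0.300, short of the threshold (permutation p = 0.056, adjusted p = 0.056), and rho 0.323 (adjusted p = 0.112). For the 372 genes with different clones r was 0.216 (permutation p = 0.00013, adjusted p = 0.00026) and rho 0.0677 (permutation p = 0.196). Genes are not independent replicates, and both filter types were hybridized with RNA of the same sublines.

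Gene lists fixed before the data were examined showed small median differences, and 0 of 28 lists passed after adjustment. Heat shock proteins and chaperones came closest, with a median of 0.27 log2 higher in LNM35 over 22 genes (permutation p = 0.0024 among random lists of matched signal, adjusted p = 0.0672); STIP1 measured 1.06 higher while DNAJB9, a chaperone of the endoplasmic reticulum, had a change of -1.11. Cholesterol and fatty acid synthesis had a median of 0.38 over 17 genes, with FDPS at 2.06 and MSMO1 at 1.09, and ribosomal proteins 0.27 over 15, with RPL7A at 1.31 and RPL10A at 0.91 (adjusted p = 0.117 for both lists). Leaving out 1 hybridization moved FDPS between 1.2 and 3.0 and RPL10A between 0.07 and 1.71. Neuroendocrine markers had a median of 0.35 over 12 genes (adjusted p = 0.117), with CPE at 1.35 and ENO2 at -1.31. NRF2 targets and aldo-keto reductases had a median of 0.16 over 29 genes (adjusted p = 0.134), with GSTP1 at 2.42 and GPX4 at 1.49. Cell cycle and mitosis genes had a median of 0.12 over 50 (adjusted p = 0.165); 3 of them met the 2-fold rule, all higher in LNM35, and the members farthest apart were RRM2 at 1.76 and UBE2C at 1.73. Without the second hybridizations the medians were -7.9e-05 for neuroendocrine markers, 0.03 for ribosomal proteins and 0.06 for the NRF2 list. The cell cycle list passed with median scaling (adjusted p = 0.0364) and with a gene's spots averaged (adjusted p = 0.0420), the NRF2 list with median scaling (adjusted p = 0.0364), and the chaperone list with spots averaged (adjusted p = 0.0420) and without the first hybridizations (adjusted p = 0.0168). Over all alternatives the adjusted p ran from 0.0364 to 0.273 for the cell cycle list, from 0.0364 to 0.627 for the NRF2 list and from 0.0168 to 0.273 for the chaperone list.

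Keratins and other intermediate filaments were the lowest list in LNM35, with a median of -0.33 over 12 genes (adjusted p = 0.117), turning to 0.08 with median scaling; KRT18 had a change of -1.18 ± 0.27 and KRT19 of -1.15 ± 0.62. Interferon-stimulated genes had a median of -0.24 over 28 genes (adjusted p = 0.162), of which 3 met the 2-fold rule, all lower; WARS1 at -3.19 and MX2 at -1.95 were farthest from 0. Angiogenic and lymphangiogenic factors had a median of -0.25 over 24 genes (adjusted p = 0.162), with FGFR2 at -1.66, where a second spot was at -0.18, and VEGFC at 1.37. Leaving out 1 hybridization moved this FGFR2 spot between -2.92 and -0.48 and VEGFC between 0.58 and 2.18. The interferon median was -0.08 without the first hybridizations, and the angiogenic median -0.04 without the second. Prostaglandin synthesis and receptor genes had a median of -0.28 over 11 genes (adjusted p = 0.421), 9 of them below 0, with TBXAS1 at -1.09 against PTGS2 at 1.37.

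The remaining lists had adjusted p-values of 0.421 or more. All 28 list medians turned or moved by over 1.5 times under at least 1 alternative. Extracellular matrix proteins had a median of -0.18, with COL16A1 at -1.53 and FMOD at -1.44, and MHC and antigen presentation genes -0.19, with HLA-F at 0.59 and PSME1 at -0.49. Leaving out 1 hybridization moved COL16A1 between -2.22 and -0.93 and FMOD between -2.12 and -0.85. Homeobox genes had a median of -0.17 over 14 genes, with PAX8 at -0.96 on GF200 and 0.22 on GF201. The median was -0.42 (adjusted p = 0.139) without the lowest 25% of spots and -0.71 (adjusted p = 0.134) without the lower 50%. Only 50% of the 14 genes lay in the upper 50% of signal, so the last median rests on few genes. The EGF receptor and MAP kinase list had -0.16, with DUSP6 at -2.23 and JUN at 1.41. Glycolysis and hypoxia genes had -0.14, with ANGPTL4 and ENO2 lowest, and apoptosis regulators -0.12, with CASP1 at -0.91 and FADD at -0.68. These 3 medians turned above 0 with median scaling, the glycolysis median also with spots averaged and the apoptosis median without the second hybridizations. ENO2 ran from -2.02 to -0.65 with 1 hybridization left out, with N15 intensities of 1.23 and 3.60. On GF200 the second N15 hybridization also read well above the first at ANGPTL4, FGFR2, PLG, FMOD, COL16A1, ZCCHC9 and DLX4. The falls of these genes lean in part on that hybridization. It read below the first at CDH11, IGFBP3, ZFYVE26, KRT19, ID4 and WNT4. Chemokines and cytokines had a median of -0.13, with IL1R2 at -1.79 against CXCL1 at 4.02 for its brightest spot, and 0.12 without the second hybridizations. Junction and adhesion genes had a median of -0.10, above 0 with median scaling and without the second hybridizations, with CLDN4 at -1.25 beside CDH11. Extracellular proteases had a median of -0.02, above 0 with median scaling, cyclic loess and an offset, and a mean of 0.04, with SERPINE2 at 1.85 and PLG at -1.38. Leaving out 1 hybridization moved SERPINE2 between 1.1 and 2.6 and PLG between -2.25 and -0.51. Medians lay between 0.01 and 0.07 for integrins and focal adhesion, with ITGB4 at 1.00 and VCL at 0.68, proteasome subunits, with PSMD2 at 2.41 and PSMA2 at 1.60, oxidative phosphorylation, with ATP5MF at 1.52 and NDUFA3 at 1.05, TGF-beta and BMP signalling, with ID2 at 2.77 and ID4 at -1.28, and Wnt and Notch signalling, with WNT5A at 1.07 and WNT4 at -1.06. Leaving out 1 hybridization moved ATP5MF between 0.50 and 2.62 and NDUFA3 between 0.65 and 1.42. On the deposited intensities the medians of integrins, oxidative phosphorylation and Wnt and Notch signalling lay below 0. The Wnt and Notch median lay below 0 also with cyclic loess, without the lower 50% of spots and without the first or the second hybridizations. The TGF-beta and BMP median was -0.14 without the first hybridizations, -0.09 with spots averaged and -0.01 without the lowest 25% or 50% of spots. Mesenchymal transition genes, CDH11 among them, had a median of 0.02, below 0 on the deposited intensities, without the lower 50% of spots and without the first hybridizations, and a mean of -0.22.

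Adjusted over the list alone, 1 gene passed by limma in each of 5 lists, against 0 over all spots: CDH11 among junction genes and among mesenchymal genes, CXCL1 among chemokines, ID2 in TGF-beta and BMP signalling and WARS1 among interferon-stimulated genes. This adjustment does not allow for the number of lists. These genes are already among those farthest apart above, so the calls add no separate evidence. Markers of other cell types lay near 0. Fibroblast and endothelial markers had a median of 0.02 over 18 genes, below 0 on the deposited intensities, without the lowest 25% or 50% of spots, without the first hybridizations and with spots averaged, with ACTA2 at 1.14 and FLT1 at 1.10 on GF200 but -0.02 and -0.36 at its GF201 spots. Leukocyte and erythrocyte markers had -0.07 over 31, above 0 with median scaling, with CD68 at 1.35, from LNM35 intensities of 0.91 and 0.11 and single ratios from -0.44 to 3.14, and the dim PTPRC at -1.32. Lung epithelial markers had a median of -0.11 and a mean of 0.03 over 14 genes, with the median above 0 without the lower 50% of spots, and with AQP4 at 1.09 and CAV1 at -0.42. The AQP4 spot lies beside a UBA1 spot that was 3.29 log2 brighter and itself measured 1.27 higher. The AQP4 spots next to UBA1 spots measured between 0.65 and 1.09 higher, and the one away from them had a change of -0.15. Over all comparisons, 36 of the 78 named spots moved by over 1.5 times when 1 hybridization was left out, and 20 read under the median of all spots in both hybridizations of the lower subline. The size of change of these 20 rests on dim signal. Besides CDH11 on GF201, PDK4, GNAS, MX2, NHLH1, PTPRC and a PTGS2 spot, these were ACTA2, CASP1, CPE, GPX4, HLA-F, IL1R2, ITGB4, PAX8, RRM2, STIP1, TBXAS1, VEGFC and WNT4.

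**Figure D3:**
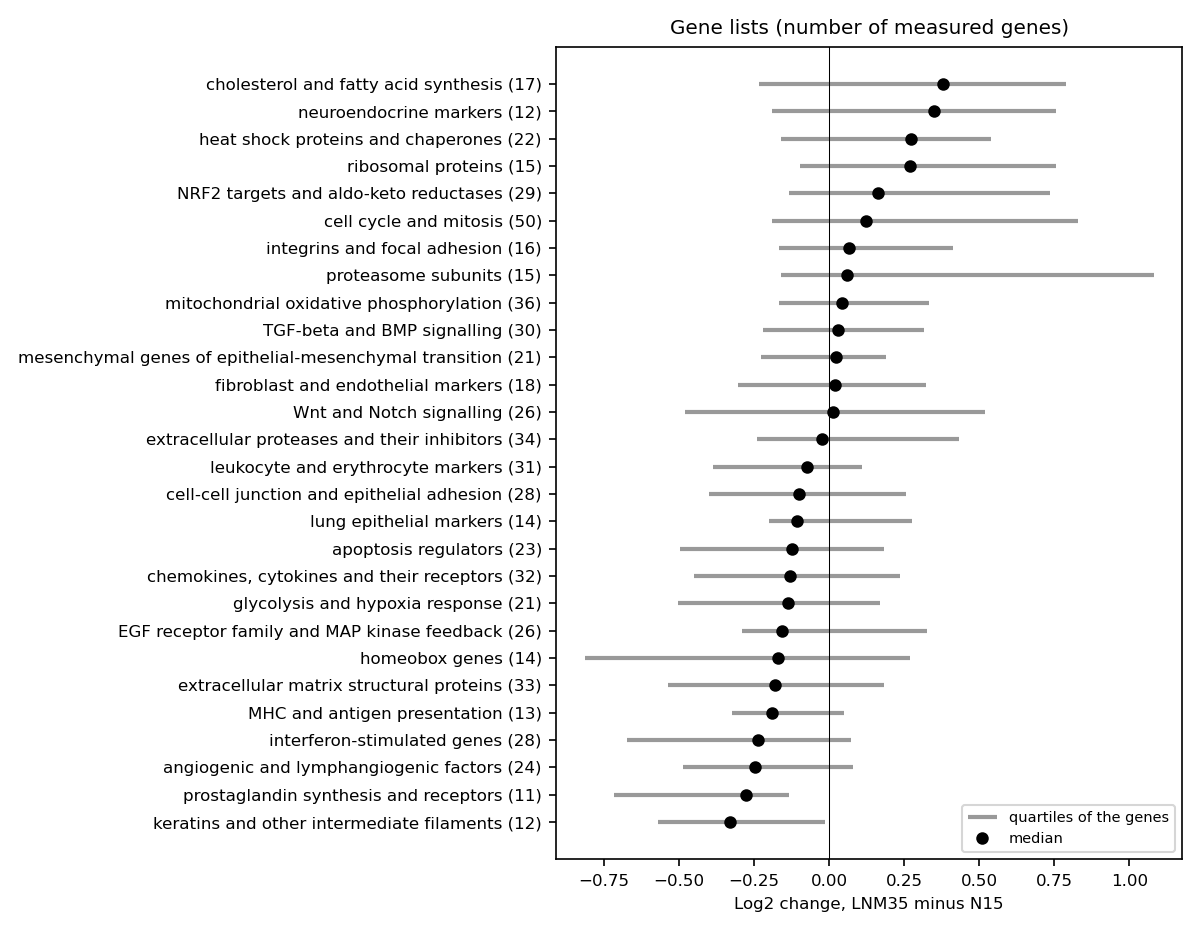
Median log2 change (LNM35 minus N15; points) and quartiles over the measured genes (bars) of the 28 lists with at least 5 measured genes. Medians run from -0.33 for keratins and other intermediate filaments to 0.38 for cholesterol and fatty acid synthesis, and 0 lists passed after adjustment.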

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

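Alternatives for chromosome 14 and for genes with several spots past the 2-fold rule were chosen after seeing the data, as was the comparison with other splits; the others were planned. For GF200, limma called 0 spots in the main analysis and 3 with median scaling. For GF201 it called 0 in the main analysis, 21 with median scaling, 7 on the deposited intensities, 1 with an offset and 13 with an intensity trend in the variance prior; the cause was not tested. The hybridization number as a replicate block gave 0 calls on GF200 and 0 on GF201; differences between the repeats correlated between sublines at 0.103 and 0.0986 across spots, and with 2 pairs the numbers are not shown to pair the hybridizations. Leaving out a hybridization, with the lone one assumed to vary like the pair of the other subline, gave 0 calls in each case on both filter types, in a fit with fewer hybridizations. Of the 116 GF200 spots past the 2-fold rule in the main analysis, the count became 233 on the deposited intensities, 39 with an offset and 76 without the lower 50% of spots, and of the 94 on GF201 it became 55, 39 and 58; an offset shrinks ratios of dim spots by construction, and fewer spots are counted without the dim ones. Leaving out a hybridization gave 338 to 790 spots on GF200 (790 without the first N15 hybridization, 421 without the second, 338 and 381 without the first and second of LNM35) and 260 to 480 on GF201 (480, 394, 306 and 260 in the same order), since fewer ratios must pass. The other 2 of 3 splits of the hybridizations gave 63 and 35 spots past this rule on GF200 and 46 and 37 on GF201; 3 splits are too few for a share under 0.05. Pearson's r of changes between filter types kept its sign and side of the threshold under all alternatives run, between 0.126 (without the first hybridizations) and 0.467; Spearman's rho, which missed the threshold in the main analysis, ran from 0.0459 to 0.300. The call on chromosome 14 ended without the first or the second hybridizations (adjusted p = 0.147 and 0.267). Past adjustment were 0 lists in the main analysis, 2 with median scaling, 2 with a gene's spots averaged, and 0 to 1 when a hybridization number was left out: the chaperone list passed without the first hybridizations (adjusted p = 0.0168). Of 252 list medians under alternatives 34 had the other sign, none of them past the threshold. Of 1070 changes of the 78 named spots under alternatives, 4 had the other sign, each with 1 hybridization left out (HLA-F, CAV1, FLT1 and DCBLD2), and 31 passed the threshold: 15 with median scaling, 8 with the trend, 7 on the deposited intensities and 1 with the offset. Dim spots repeat less well than bright ones, and 20 of the 78 named spots sit beside a spot at least 2 log2 brighter.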

Other observations

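The tests of random placement for chromosome 14, of the ATF4 list and of the segment around PSMD2 were chosen after the values they use had been seen; the others were set before. On GF201, TMSB4X, encoding the actin-binding thymosin beta 4, measured 2.30 log2 higher in LNM35 at high signal, with intensities of 40.97 and 15.19 against 5.08 and 3.62 in N15. DNER, a Notch ligand gene, measured 1.95 higher and NFKBIZ, a nuclear regulator of NF-kappa-B target genes such as chemokines, 2.20 higher, from N15 intensities of 0.13 and 0.06 under the N15 medians of 0.18 and 0.17. All 3 passed by limma with median scaling (adjusted p = 0.0012 for TMSB4X, 0.0130 for DNER and 0.0141 for NFKBIZ), TMSB4X also with an intensity trend (adjusted p = 0.0084), and none in the main analysis; these genes were chosen after their values were seen.

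Genes of chromosome 14 were lower in LNM35 as a group: the median log2 change of its 206 measured genes was -0.20 and 68.9% of them were below 0, against medians between -0.13 and 0.12 on the other 22 chromosomes tested. Random placement of noisy genes is argued against by an adjusted p of 0.0046 over 23 chromosomes among gene sets matched on filter type and signal (permutation p = 0.0002, the smallest the random sets can give); over 23 chromosomes the adjusted p was 0.0437 or less under the alternatives that keep all hybridizations, but 0.147 without the first hybridizations (median -0.19) and 0.267 without the second (median -0.13), so the call rests on having both, and the median itself was -0.07 with median scaling and -0.39 on the deposited intensities. Medians of -0.20 on GF200 (permutation p = 0.0056) and -0.13 on GF201 (permutation p = 0.021) argue against an error of one filter type alone. These p-values, like the one for the weaker side below, are unadjusted and reuse the values that singled out the chromosome. On GF200, medians of single ratios were -0.11 and -0.045 over the first N15 hybridization and -0.27 and -0.27 over the second. Those on GF201 lay between -0.29 and -0.12. A lower copy number of the whole chromosome in LNM35, or a higher one in N15, may underlie the pattern: split in the middle of its genes in order of position, the chromosome had medians of -0.17 and -0.29, with permutation p = 0.012 for the weaker side. WARS1, LGALS3 and ZFYVE26 lie on this chromosome; no DNA measurement was used here, so the copy number explanation remains a hypothesis.

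The 4 aminoacyl-tRNA synthetase genes low in LNM35, WARS1, GARS1, SARS1 and AARS1, are known targets of the amino acid response driven by ATF4. A low region of the filter is argued against, since the 160 spots within 20 positions of theirs had a median change of -0.0060 ± 0.036 (SE). A weaker ATF4 response in LNM35 could account for the group, but the other 18 measured genes of an ATF4 list had a median of -0.0783 (permutation p = 0.701 among random lists) and 9 of them were below 0, so the test left this open. Those 18 ran from ATF3 at -1.41 to STC2 at 1.05, with quartiles of -0.82 and 0.22, so their spread reached farther below 0 than above it. The other 7 measured cytosolic synthetases, which include HARS1, QARS1, FARSA, KARS1 and VARS1, had a median of -0.05 and lay between -0.34 and 0.51.

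PSMD2 and ALG3, both high in LNM35, are neighbours on chromosome 3 with no measured gene between them. Signal spilling over from neighbouring spots is argued against for these genes. The 12 spots next to theirs had a median change of 0.157 ± 0.260 (SE), while their own 6 spots measured 1.49 or more higher. Across all spots, however, log2 changes of spots 1 position apart correlated at 0.199 on GF200 and 0.081 on GF201. At 50 positions apart the correlations were 0.002 and -0.005. Sharing of signal between neighbours elsewhere on the filters is therefore not excluded. A gain of a wide segment that raised its genes alike is argued against as the whole cause. The 10 measured genes on each side had a median of -0.103 (permutation p = 0.590), an upper quartile of 0.23 and a highest change of 0.68. Genes that these cells do not express could not respond to a gain, and expression of each was not tested. A gain with unequal effects on its genes is therefore not excluded. A change limited to the closest genes, where the nearest measured ones were DVL3 at 0.48 and ABCF3 at 0.52 on one side and EPHB3 at 0.66 and TRA2B at 0.68 on the other (limma p between 0.0978 and 0.409, unadjusted), or shared regulation of PSMD2 and ALG3, may explain the pair and was not tested.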
